A study of Alishewanella jeotgali and Alishewanella aestuarii and Alishewanella agri with 4 samples.

How the data were processed

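RNA of 4 cultures was sequenced as 36-base single-end reads on an Illumina Genome Analyzer IIx, per the labels' protocols. The protocols state that the RNA came from stationary cells, was purified with an RNeasy Mini kit and was depleted of rRNA with a MICROBExpress kit before sequencing. CASAVA 1.6 is the only tool named, per the submitters' processing notes. The aligner, the genome builds, the counting method, its use of strand and any filter on reads are not given in the sources used here.

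The deposited tables give 1 value per feature and library in RPKM (reads per kilobase of gene, scaled to the reads of the library), a unit named per the file headers of A. aestuarii and A. agri. The headers of the A. jeotgali table name no unit for its pectin and succinate columns. These columns were read as RPKM because value times length, divided by 1000 and summed over features, gave the total that RPKM implies, and because each value was a whole number of reads at a single library total (tolerance 0.003 reads). That total gave the number of reads counted in each library. The authors' deposited table for A. jeotgali also holds a fold change column, pectin over succinate, per the file headers. That column equalled the quotient of the pectin and succinate values of the same row for 100% of the 3731 features with a ratio (tolerance 0.011), so the authors computed it on the rows as deposited. The same A. jeotgali table was deposited for both samples of that species and was used once. Lengths are coding lengths, and the files give contig names but no build.

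In the A. jeotgali table the succinate column was found, on looking at the values, to stand in another row order than the genes. With the rows as deposited, 2.78% of its values were whole reads at the library total of the restored order, and no more at the total found from the deposited rows. In the order of region end positions 100% were, and the sum of values times lengths then met that total, which it passed 1.22-fold as deposited. This order was 1 of 256 tried, 16 of them by region end and 240 by other keys, of which the best made 8.85% of the values whole. Ties at a shared region end (94 features) were broken by start, and 5 features share both start and end. Of these 5, 2 were above zero, with at most 6.30 RPKM. Every succinate value below comes from the restored order unless the authors' deposited table is named.

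From the RPKM values, a log2 ratio was computed for each gene of each of 6 contrasts, with 1 added to both values, and folds are powers of these ratios. A gene was called higher or lower when its log2 ratio was at least 1 in size and its mean was at least 10 RPKM. Each group has 1 library, so the differences have no replicate check, no test between conditions was possible and no p-value was computed. The 95% intervals are exact conditional (Clopper-Pearson) intervals on the 2 read counts, without the added 1. They cover counting error in the 2 libraries only. The libraries hold 3765392 reads in features for A. jeotgali on succinate, 2730927 for A. jeotgali on pectin, 5204477 for A. aestuarii and 2881607 for A. agri. The median protein gene has 779, 488, 830 and 628 reads in that order. With 3 reads as the floor, a gene of 1 kb would have 0.797, 1.10, 0.576 and 1.04 RPKM in the A. jeotgali succinate, A. jeotgali pectin, A. aestuarii and A. agri libraries.

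Genes of the 3 species were paired as reciprocal best protein hits with BLAST+ 2.17.0 (e-value at most 1e-5, at least 60% identity over at least 70% of the shorter protein). The deposited tables of the species were normalized separately. Folds between species are therefore ratios of shares of different gene sets.

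Gene lists were made by matching product texts to 23 fixed patterns. The lists cover pectin depolymerisation, galacturonate catabolism, side-chain glycoside hydrolases, TonB-dependent receptors, TonB and ExbB/ExbD proteins, dicarboxylate transporters, the TCA cycle, the glyoxylate shunt with gluconeogenesis, and glycolysis with the Entner-Doudoroff pathway. They also cover the respiratory chain, ATP synthase, ribosomal proteins, chaperones, oxidative stress, starvation, flagella, type II secretion with pili, iron, fatty acid oxidation and denitrification. The last 3 hold GntR, LacI and IclR regulators, phage and transposable elements, and rRNA with tRNA genes. As a departure from the fixed plan, a gene also entered a list when the product text of its ortholog matched, since many A. jeotgali genes are annotated as hypothetical. As a further departure, mannosaminuronate enzymes and matches of relA within the word related were left out of all lists. Products with synthase, methylase, alanine, glutamic or processing in their text were left out of the ribosomal protein list. Other members that matched by text only were kept, and some that are known to act elsewhere are named in the text. Each list's median log2 ratio has a percentile among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins, as a description of these libraries.

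Contrasts, list patterns, thresholds and the alternatives given here were fixed before the data were examined. The ortholog rule for lists and 3 further alternatives were added later, and the exclusions from lists named as a departure were not in the fixed plan. The rule for the genes named in each contrast was fixed with the contrasts. It took the 10 largest and 10 smallest ratios with an informative product (5 and 5 between species) and every measured member of the pectin depolymerisation and galacturonate lists. Of each other list it took the member with the highest mean and the one with the ratio of largest size. Alternatives were a pseudocount of 0.1 or 5, a minimum of none or 50 RPKM, a 4-fold threshold, 80% identity of orthologs and pairing by unique product text. For scaling they were the median ratio, a trimmed mean of log ratios (30% of ratios and 5% of levels), and totals without RNA genes and the 20 most abundant genes.

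The calls were tested on simulated data, with reads drawn for the real genes and 50 genes set to each fold. In the contrast of A. jeotgali on pectin and succinate (3739 genes), 0% of genes set to 1.5-fold, 46% of those set to 2-fold and 100% of those set to 3-fold or 4-fold were called. There, 3 of 3519 unchanged genes were called and the intervals covered 95.3% of the true folds. Counting error was the only spread in these data, so both values leave out variation between cultures and libraries. With a spread per library of 0.23 to 0.60 log2 units added, simulated unchanged sets of 4 libraries had 76.7 higher genes per contrast on average. These spreads were solved from the ratios between these same libraries, so they include differences of species and carbon source. The average is over the 3 contrasts with the succinate library, with the largest spread for A. agri. It is no noise level for the A. jeotgali contrast alone. The check of the row order (3739 genes) put 100% of reordered rows back. It reversed the same sort that had reordered them, so this outcome was fixed beforehand and is no support for the restored order. The computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.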

Results

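Transcripts of 3 Alishewanella species, A. jeotgali, A. aestuarii and A. agri, grown on pectin were compared with those of A. jeotgali grown on succinate. Pectin is a plant polysaccharide built largely of galacturonic acid, whereas succinate enters metabolism directly as an intermediate of the TCA cycle. The question was which genes differ in level when the cells live on pectin. Each group has 1 library, so every difference below is a difference between libraries. The tables list 3669 protein genes for A. jeotgali, 3380 for A. aestuarii and 3159 for A. agri, of which 2, 0 and 0 had no reads.

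The succinate values of A. jeotgali were used in a restored row order, because in the deposited order 2.78% of them were whole reads and in the restored order 100%. Across genes, which are not independent replicates, the log2 values of the pectin and succinate libraries had a Pearson correlation of 0.0142 in the deposited order and 0.718 in the restored order. All 6 rRNA features of the A. jeotgali table were listed at 0 in the pectin library, and they were at 0 in the succinate library only in the restored order. The fold changes in the authors' deposited table were computed on the deposited rows. In the authors' deposited table, altronate dehydratase (uxaA) has a fold of 22.43 and altronate oxidoreductase (uxaB) a fold of 11.98, against 24 and 12.9 here. The succinate values behind those folds in the authors' deposited table, 226 and 190.2 RPKM, belong to other genes in the restored order. The succinate values had a median of 251 RPKM and an interquartile range of 0.62 on the log2 scale.

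**Figure D1:**
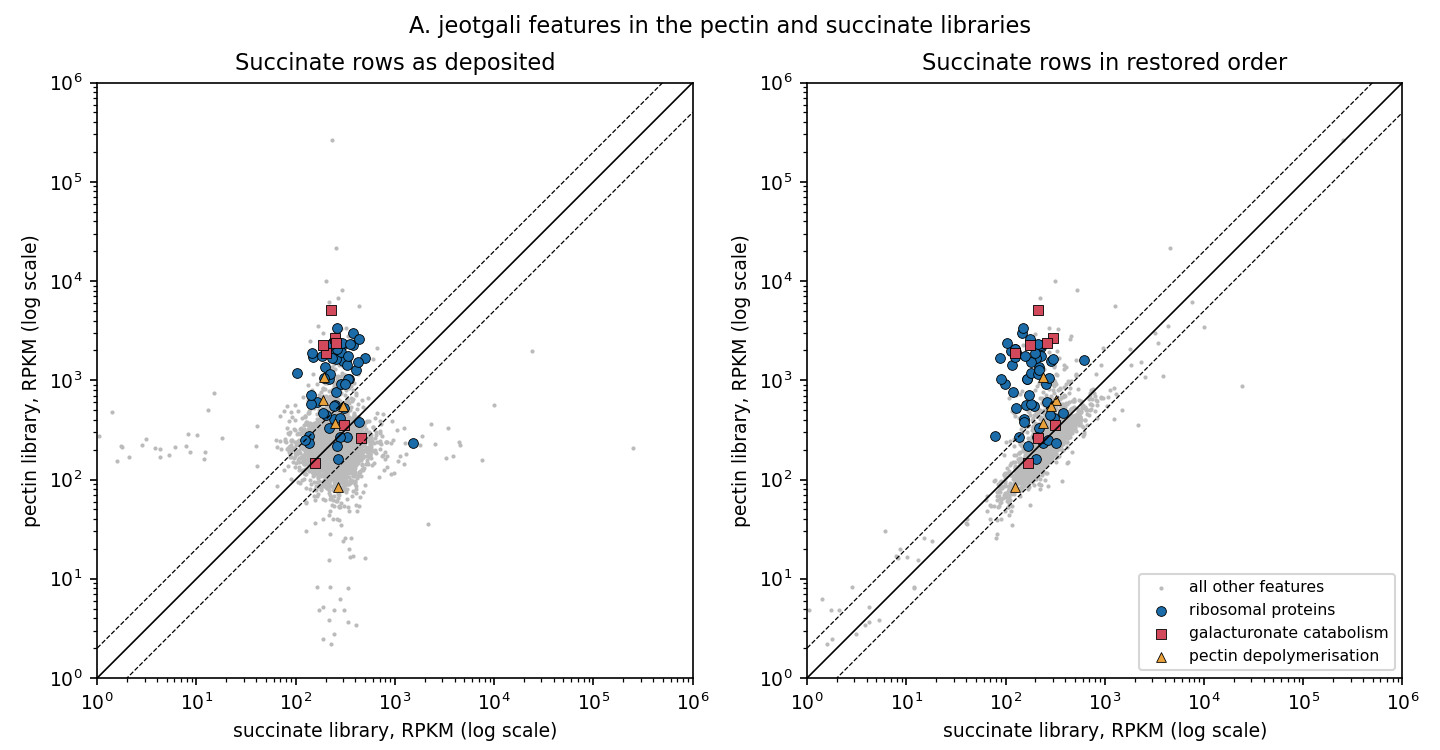
RPKM of each A. jeotgali feature in the succinate library (horizontal, log scale) and the pectin library (vertical, log scale), with the succinate rows as deposited (left) and in restored order (right). Dashed lines mark 2-fold differences; in restored order most features follow the diagonal, with ribosomal protein and galacturonate genes above it.

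In A. jeotgali, the genes that turn galacturonate into central metabolites were among the features with the largest ratios between pectin and succinate. Altronate dehydratase (uxaA, AJE_10200), which removes water from altronate to give 2-keto-3-deoxygluconate, was at 5063 RPKM on pectin and 209.9 RPKM on succinate, 24-fold higher (95% interval 22.8 to 25.6). The aldolase KdgA (AJE_10170), which splits the phosphorylated product into pyruvate and glyceraldehyde 3-phosphate, was 14.8-fold higher (13.3 to 16.9). Altronate oxidoreductase (uxaB, AJE_10180) was 12.9-fold higher (12.2 to 13.9), the isomerase uxaC (AJE_10190) 9.16-fold (8.69 to 9.72) and the kinase kdgK (AJE_10160) 8.78-fold (8.26 to 9.40). These 5 genes carry out the isomerase pathway from galacturonate to pyruvate. The other members of the list stayed under 2-fold. KduI (AJE_10280) and KduD (AJE_10290), which handle the unsaturated product of pectate lyases, were 1.24-fold and 1.13-fold higher. A further aldolase of the KdgA kind (AJE_01390) was 1.14-fold lower, with an interval of 0.973 to 1.34 that includes 1. The median log2 ratio of all genes was −0.28, and list medians for this contrast are given relative to it. The 8 galacturonate genes had a relative median of 3.44, at percentile 99.96 of random lists.

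Genes of the pectin depolymerisation list differed less. A glycoside hydrolase of family 28 (AJE_10210), the family of polygalacturonases, was at 1073 RPKM on pectin and 239 RPKM on succinate, 4.47-fold higher (4.21 to 4.77). The unsaturated rhamnogalacturonyl hydrolase urh105A (AJE_10320) was 1.98-fold higher (1.89 to 2.07), a protein annotated as pectate lyase in its ortholog (AJE_15310) 1.92-fold (1.81 to 2.03) and the pectin methylesterase pmeA (AJE_10330) 1.57-fold (1.44 to 1.72). Another gene with a pectate lyase ortholog, AJE_32120, which overlaps another listed gene by 20 bases, was 1.46-fold lower (1.15 to 1.87). So 1 of 5 pectin depolymerisation genes was at least 2-fold higher before rescaling and 3 of 5 after rescaling by the median ratio. The list had a relative median of 1.22, at percentile 97.4 and thus just inside the central 95% of random lists.

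Many of these genes are neighbors. A stretch of 23.8 kb holds 20 genes that run from a glyceraldehyde-3-phosphate dehydrogenase (AJE_10150), through kdgK, kdgA, uxaB, uxaC, uxaA and the family 28 hydrolase, to urh105A, pmeA and a GntR regulator; the stretch was chosen after its values were seen. Of its 20 genes, 8 were at least 2-fold higher on pectin, and these 8 include the dehydrogenase (4.50-fold, 4.28 to 4.75) and a LacI regulator (AJE_10230, 2.75-fold, 2.55 to 2.98). As called, the 8 are grouped at the kdgK end. After rescaling by the median ratio, AJE_10240 (1.87-fold before it), AJE_10250 (1.94-fold), the receptor AJE_10310 (1.94-fold) and urh105A (1.98-fold) would pass 2-fold too. The grouping thus depends on the scaling. Toward the other end, the TRAP transporter genes dctM (AJE_10250) and dctQ (AJE_10260), whose kind imports acidic sugars and dicarboxylates, were 1.94-fold and 1.25-fold higher. The neighboring AJE_10270 counted as a ribosomal protein by its annotation, yet its ortholog is the binding protein of a TRAP transporter.

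**Figure D2:**
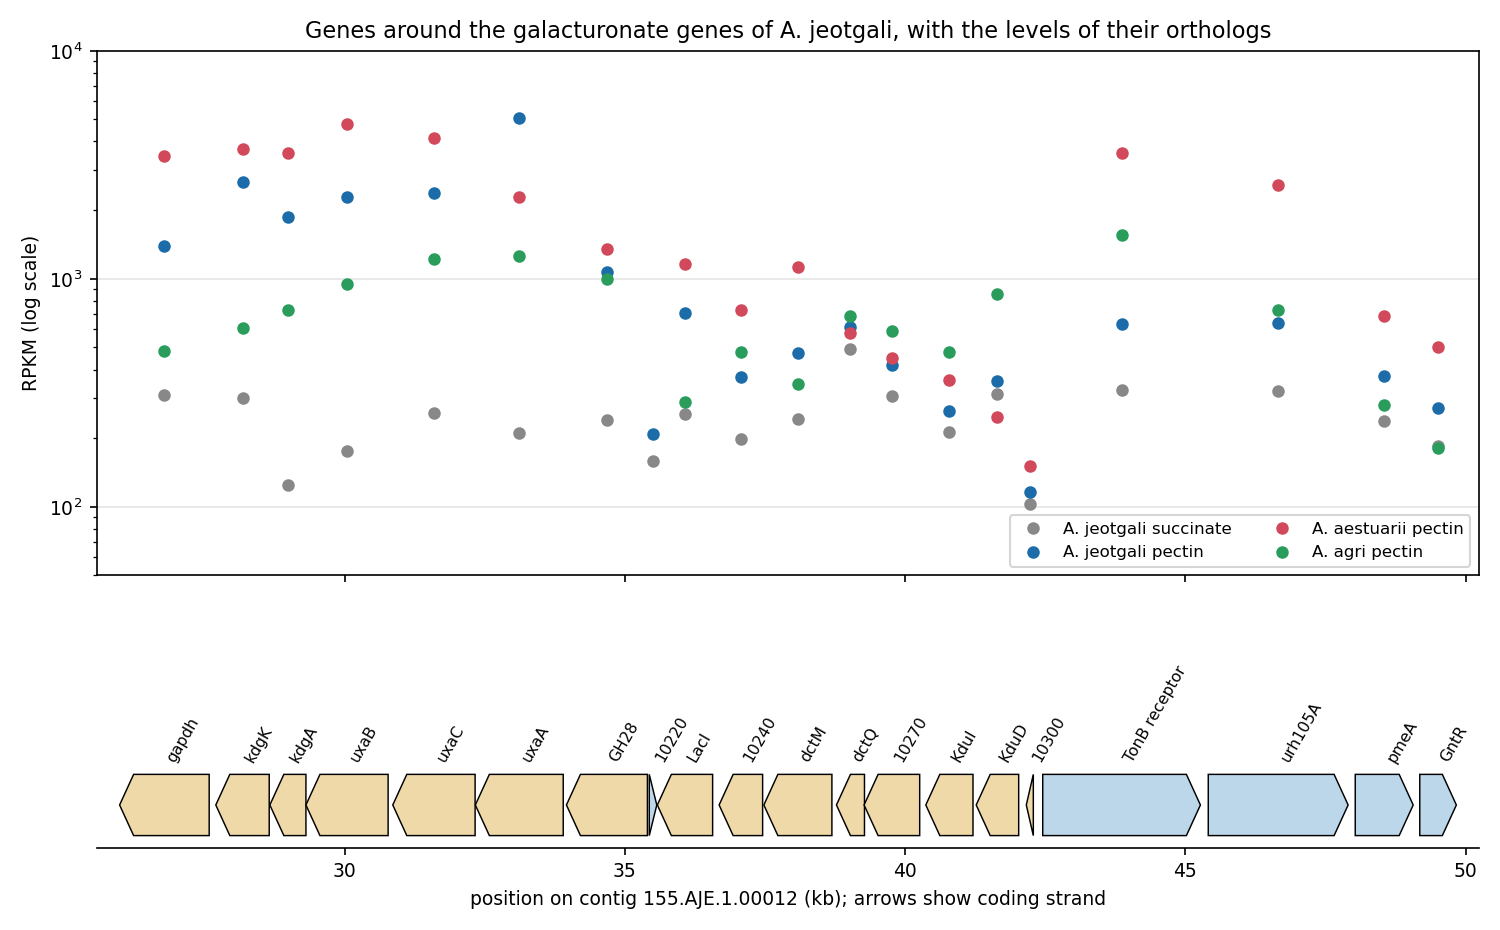
RPKM (log scale, upper panel) of the genes around the galacturonate genes of A. jeotgali and of their orthologs in each library, over the gene map (lower panel, position in kb on the contig, arrows by coding strand). The genes from gapdh to GH28 lie above their succinate level in all 3 pectin libraries.

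Ribosomal protein genes formed the largest group of higher genes in A. jeotgali. Of 55 listed, 44 were at least 2-fold higher on pectin and 0 were lower, and the list's median level was 1169 RPKM on pectin and 179 RPKM on succinate. S11 (AJE_21500) was 22.7-fold higher, S4 (AJE_21510) 22.1-fold, L30 (AJE_21460) 19.96-fold, L18 (AJE_21440) 18.9-fold and S12 (AJE_21230) 17.3-fold, and L16 (AJE_21350) and L6 (AJE_21430) were each 16.5-fold higher. The relative median of the list was 2.91, above that of every random list. Genes of the same clusters that are not ribosomal proteins were read from the overlap of all species and were thus chosen after their values were seen. Among them, RNA polymerase subunit alpha (AJE_21520) was at 3377 RPKM on pectin and 277 RPKM on succinate, and SecY (AJE_21480) at 2894 RPKM and 198 RPKM.

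Central carbon metabolism differed at particular steps. Isocitrate lyase (AJE_09100), the entry to the glyoxylate shunt by which cells save carbon from acetyl units, was at 10015 RPKM on pectin and 316 RPKM on succinate. Its ratio of 31.6 (30.2 to 33.2) was the highest among genes with an informative product. In the glyoxylate and gluconeogenesis list, 2 of 10 members were higher and the relative median was 0.09 (−0.19 before rescaling, so its direction flips with scaling). Of 22 TCA cycle genes, 6 were higher and 0 lower, with a relative median of 0.51 above that of every random list. The E2 subunit of 2-oxoglutarate dehydrogenase (AJE_34730) was 5.51-fold higher (5.06 to 6.09) and succinyl-CoA synthetase alpha (sucD, AJE_34750) 5.26-fold (4.87 to 5.74). The TCA list holds a few enzymes matched by name, such as methylcitrate and isopropylmalate enzymes, that serve other pathways. Of 20 glycolysis and Entner-Doudoroff genes, 2 were higher, 1 of them the dehydrogenase next to kdgK, at a relative median of 0.07 that is −0.21 before rescaling. NqrF (AJE_27290), part of a sodium pump fed by NADH, was 5.25-fold higher as the only called member of 25 respiratory chain genes (relative median 0.16, but −0.12 before rescaling). ATP synthase genes had a relative median of 0.82 (percentile 99.99) with 2 of 10 higher; the epsilon subunit (AJE_18690) was 2.13-fold higher (1.82 to 2.51). That list includes the flagellar export protein FliI, which resembles an ATP synthase subunit.

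Genes of peroxide defence also differed, while the uptake lists held few called genes. AhpC (AJE_17500), a peroxidase that removes hydrogen peroxide and organic peroxides, was at 6715 RPKM on pectin and 225 RPKM on succinate, 29.7-fold higher (27.3 to 32.8). Of 20 oxidative stress genes, 6 were higher and 0 lower (relative median 0.31, percentile 98.5). Among 27 chaperones 9 were higher and 0 lower (relative median 0.29, percentile 99.5); the largest ratio in that list, 5.87-fold, belonged to a cold-shock protein (AJE_04200), which binds RNA and does not fold proteins. The peptidoglycan-associated lipoprotein Pal (AJE_32580), which ties the outer membrane to the cell wall, was 14.9-fold higher (13.3 to 17.0). Pal stood in the phage list only because the text of an ortholog mentions phage DNA. A biopolymer transport protein (AJE_06640) was 3.18-fold higher (2.80 to 3.64), 1 of 2 higher genes among 5 of the TonB and ExbB/ExbD list (relative median 1.20, percentile 74.9). Of 23 TonB-dependent receptors, 1 was higher (AJE_30280, 3.55-fold, 3.37 to 3.76) and the relative median was −0.07. The receptor AJE_10310, at 1.94-fold, would pass 2-fold after rescaling by the median ratio.

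The remaining lists held few called genes. The median protein gene was at 73.8% on pectin and 86.3% on succinate of the RPKM that an even spread of reads over features would give. An even background of reads was not measured, and it could hide differences in genes near the median. Among 7 iron genes 2 were higher, with ferritin (AJE_01410) at 2.94-fold (2.56 to 3.40) and a relative median of 0.26 (−0.02 before rescaling). Of 9 starvation genes, 1 was higher, AJE_15330, whose ortholog is a ribosomal subunit interface protein (2.66-fold), at a relative median of 0.10 (−0.18 before rescaling). Ribosome modulation factor (AJE_01190), which pairs idle ribosomes, was at 6215 RPKM on pectin and 7591 RPKM on succinate. The list of side-chain glycoside hydrolases took in mostly amylases and glucosidases, which act on starch and other glucans, so it does not describe pectin side chains. It had 1 of 12 higher (relative median −0.03), the family 28 enzyme already named. The 7 dicarboxylate transporters held no called gene (relative median 0.26, −0.02 before rescaling), nor did the 26 genes of type II secretion and pili (−0.04) or the 11 of fatty acid oxidation (0.24 relative at percentile 99.2, −0.04 before rescaling). The 8 denitrification genes held none either, with a relative median of −0.23 at percentile 0.49. After rescaling by the median ratio, dctM of the dicarboxylate list (1.94-fold before it) would pass 2-fold. Of 10 GntR, LacI and IclR regulators, the LacI gene near uxaA was the 1 higher (relative median −0.02). The 64 measured tRNA genes had 3 higher and 3 lower, at 0.11 relative and −0.16 before rescaling, at percentile 99.4. The directions of these lists with values of both signs thus depend on scaling.

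Fewer A. jeotgali genes were lower on pectin. A flagellin-like gene (AJE_07530) was at 352 RPKM on pectin and 2174 RPKM on succinate, 6.17-fold lower (5.76 to 6.64). It was the 1 lower gene among 73 flagella and chemotaxis genes, whose median was −0.15, and 0.13 relative to all genes, so that the list's direction depends on scaling. Its percentile was 98.1, and inside the central 95% of random lists after rescaling by the median ratio. The purine biosynthesis enzyme purH (AJE_26280) was 2.47-fold lower (2.30 to 2.67), and a cold-shock protein (AJE_30040) was 2.38-fold lower (2.16 to 2.62). A heavy-metal regulator (AJE_21880) was 2.72-fold lower (1.83 to 4.21) and a heavy metal detoxification gene (AJE_21900) 2.48-fold. Of the 10 smallest ratios, 4 were reverse transcriptases, 2.83-fold to 3.03-fold lower. They share 36-base stretches with other copies, which makes their values uncertain. Of 75 measured phage and transposable element genes, 4 were higher and 3 lower, with a relative median of −0.11 at percentile 0.025.

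In total, 171 of 3719 A. jeotgali features were at least 2-fold higher on pectin and 43 at least 2-fold lower; after rescaling by the median ratio the split was 215 and 20. At 4-fold, 75 were higher and 2 lower. Of the higher and lower features, 45 and 25 have no informative product. Folds differed in size beyond counting error for each called gene, but variation between cultures was not measured. The succinate library had a narrower spread, with a 95th percentile over median of 1.75 against 2.63 on pectin, and the folds of galacturonate genes, isocitrate lyase and AhpC rest on it like those of ribosomal proteins.

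**Figure D3:**
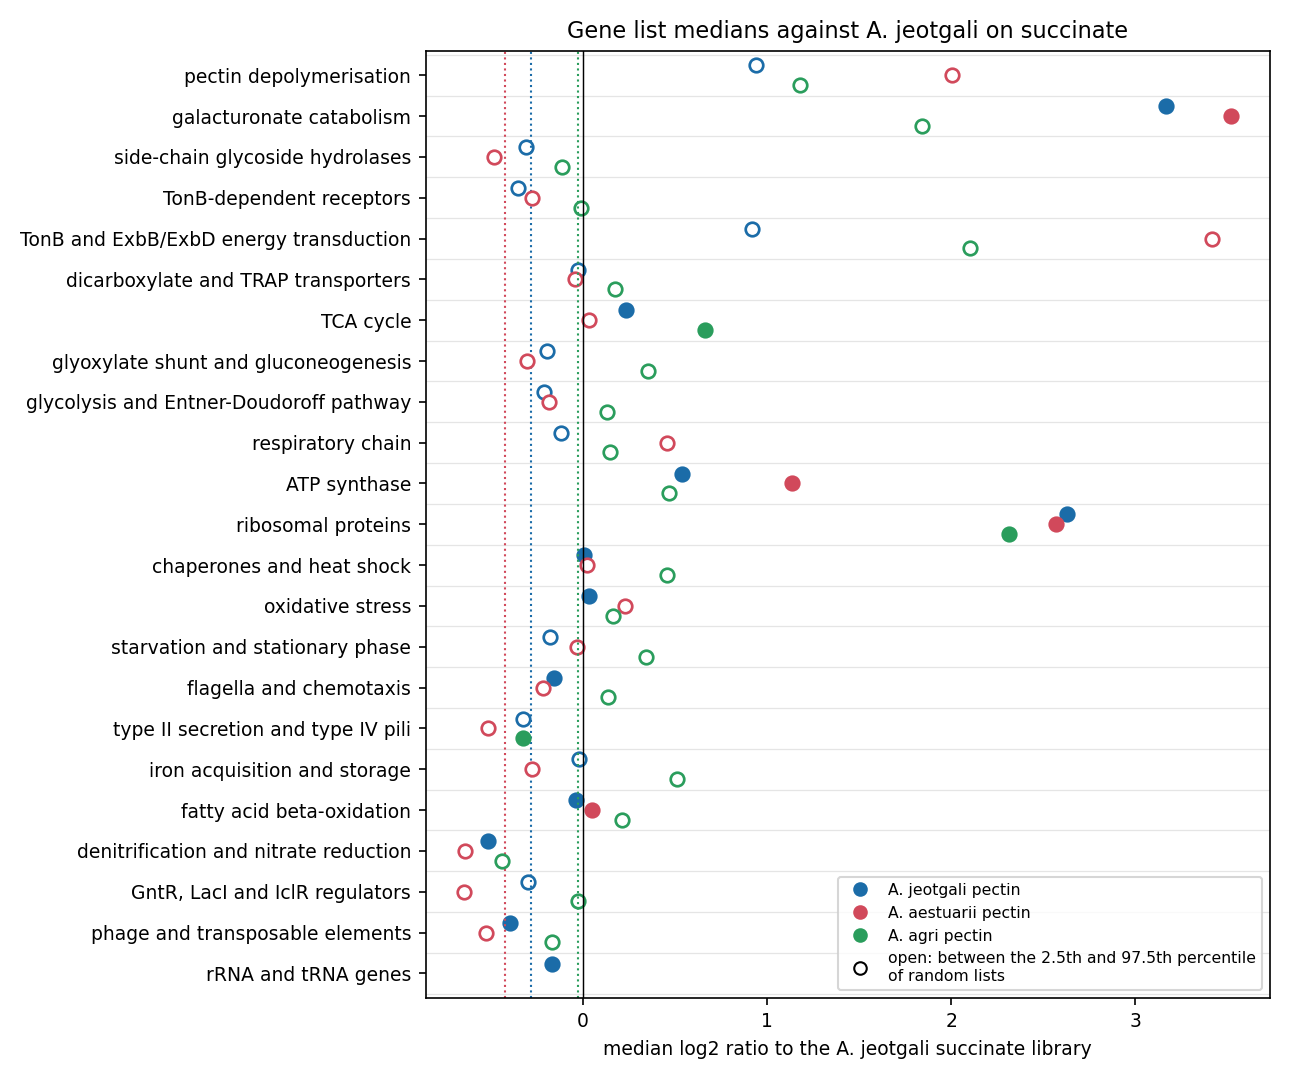
Median log2 ratio to the A. jeotgali succinate library (horizontal) of each gene list in the 3 pectin libraries; filled points lie outside the central 95% of random lists, and dotted lines mark the median of all genes. The galacturonate and ribosomal protein lists lie farthest to the right for A. jeotgali, while the lists between them and 0 change place between species.

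A. aestuarii on pectin had the same galacturonate pathway at high levels relative to A. jeotgali on succinate. KdgA (AEST_20020) was at 3563 RPKM against 125 RPKM, 28.2-fold higher (25.4 to 32), uxaB (AEST_20030) was 27.0-fold higher (25.5 to 29.0), uxaC 15.9-fold, kdgK 12.2-fold and uxaA 10.8-fold. Urh105A (AEST_20160), which acts on rhamnogalacturonan fragments, was 7.98-fold higher (7.71 to 8.30), the family 28 hydrolase 5.64-fold and pmeA 2.86-fold. The pectate lyase AEST_12700 was 1.20-fold lower with an interval that includes 1 (0.986 to 1.46). A TonB-dependent receptor beside urh105A (AEST_20150), the kind of outer membrane protein that imports large ligands, was 10.9-fold higher (10.6 to 11.3). SucD (AEST_15750) was at 5922 RPKM against 222 RPKM, 26.6-fold higher (24.8 to 28.7); it overlaps another listed gene by 36 bases. Catalase (AEST_24930) was 18.4-fold higher, AhpC 23.3-fold, the epsilon subunit of ATP synthase 14.6-fold, Pal (AEST_13290) 32-fold and ribosomal protein S4 32.9-fold. KduI was 1.70-fold higher and KduD 1.26-fold lower, the further aldolase AEST_17960 1.59-fold higher. Transposases with ratios of 44.5 (AEST_28940) and 30.5 (AEST_01020) share all their 36-base windows with other copies, so their values are uncertain.

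All genes together had a median log2 ratio of −0.42, and relative to it the galacturonate list stood at 3.94 (5 of 8 higher) and ribosomal proteins at 2.99 (44 of 52). Relative medians were 2.43 for pectin depolymerisation (3 of 4 higher), 3.84 for TonB and ExbB/ExbD proteins (4 of 5) and 1.56 for ATP synthase (5 of 10 higher, 1 lower). The respiratory chain stood at 0.88 (5 of 24 higher). The TCA cycle list, which holds sucD, had 6 of 22 higher and 2 lower (relative median 0.46, percentile 93.6), and TonB-dependent receptors had 3 of 16 higher (percentile 56.7; relative median 0.15, but −0.28 before rescaling). Above the central 95% of random lists were the galacturonate (99.5), ribosomal (99.9), ATP synthase (99.99) and fatty acid (99.2) lists. The flagellin AEST_29350, with 61.7% of its 36-base windows in other genes and so uncertain, was 8.57-fold lower (8.07 to 9.17), the secretion gene for GspH (AEST_20400) 3.53-fold lower and a glyoxalase (AEST_03340) 5.68-fold lower. Type II secretion and pili had 1 of 24 higher and 6 lower. Among 2752 orthologs, 189 were at least 2-fold higher and 325 at least 2-fold lower, a split of 294 and 88 after rescaling by the median ratio. Species and carbon source differ together in this contrast, and the tables of the species were normalized separately.

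A. agri on pectin had smaller ratios to the succinate library than the other species for kdgK, kdgA, uxaB, uxaC and uxaA, while more members of the galacturonate list were called. UxaA (AGRI_15005) was 6.0-fold higher (5.67 to 6.41), kdgA (AGRI_15020) 5.82-fold (5.17 to 6.65), uxaB 5.40-fold, uxaC 4.69-fold and kdgK 2.02-fold (1.88 to 2.19). Here KduD (AGRI_14965) at 2.73-fold (2.53 to 2.97) and KduI (AGRI_14970) at 2.25-fold (2.05 to 2.48) were higher too, so that 7 of 8 members were called. The family 28 hydrolase was 4.17-fold higher (3.93 to 4.46), the pectate lyase AGRI_09540 2.59-fold (2.46 to 2.73) and urh105A 2.26-fold (2.17 to 2.37). The pectate lyase AGRI_05257 was 1.59-fold, pmeA 1.18-fold and the further aldolase AGRI_02820 1.07-fold higher. Isocitrate lyase (AGRI_15475) was at 6161 RPKM against 316 RPKM, 19.4-fold higher (18.6 to 20.4), and a cold-shock protein (AGRI_01350) 16.7-fold higher (15.0 to 18.7). A protein related to RseA (AGRI_07505), which restrains the envelope stress sigma factor RpoE, was 18.8-fold higher (17.1 to 20.8).

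The TCA cycle list had 7 of 22 higher, 0 lower and a median of 0.67 (percentile 99.9); aconitase (AGRI_13236) was 3.56-fold higher. Ribosomal proteins had 51 of 55 higher and 1 lower (median 2.31). The galacturonate median was 1.84 (percentile 95.4), that of pectin depolymerisation 1.18 (percentile 83.2) and that of TonB and ExbB/ExbD proteins 2.10 (percentile 58.0), with ExbB (AGRI_00645) 6.0-fold higher. These medians exceed that of the TCA cycle list at lower percentiles, since random lists are matched on the mean of both libraries. Outside the central 95% of random lists were the TCA cycle, ribosomal protein and type II secretion lists. Flagella and chemotaxis had 11 of 68 higher and 6 lower, while type II secretion and pili had 1 of 25 higher and 3 lower (median −0.33, percentile 0.89). A flagellin-like gene (AGRI_00245) was 23.1-fold lower (20.5 to 26.9) and ribosome modulation factor (AGRI_02730) 3.97-fold lower (3.72 to 4.26). The hypothetical gene AGRI_00895, chosen after its value was seen, was at 741 RPKM against 24076 RPKM, 32.4-fold lower (30.1 to 35.1). The largest ratio, 215-fold, belonged to an IS1668 transposase (AGRI_00005) all of whose 36-base windows occur in other listed copies, which leaves its value uncertain. Among 2620 orthologs, 296 were higher and 238 lower, with a median of all genes of −0.03.

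Genes higher in all 3 pectin libraries than in A. jeotgali on succinate included those of translation, galacturonate use and the TCA cycle. Species and carbon source differ together in 2 of these 3 contrasts, since only A. jeotgali has a succinate library. Of 2477 genes with orthologs in all 3 species, 91 were at least 2-fold higher in each pectin library than in the succinate library, and 40 at least 4-fold. Ribosomal proteins made up 43 of the 91, and 5 were the galacturonate genes kdgK, kdgA, uxaB, uxaC and uxaA. Another 5 were TCA cycle genes, among them succinate dehydrogenase (AJE_34710), at 219 RPKM on succinate and 1099.6, 1004 and 635 RPKM on pectin in A. jeotgali, A. aestuarii and A. agri. Malate synthase A (AJE_09120) joined isocitrate lyase, and the chaperone DnaK (AJE_10090), AhpC, Pal, ferritin, elongation factor Tu (AJE_21140) and the family 28 hydrolase were also among the 91. Only 3 were lower in all: AJE_06000, the flagellin-like AJE_07530 and purH. The 3 lists of higher genes held 153, 173 and 286 genes, and lists of these sizes drawn independently would share 1.23. With a common reference library, 1000 simulated sets of unchanged libraries with a spread per library shared 1.82 on average and 8 at most; their lists were shorter than the real ones, with 76.7 higher genes per contrast on average. For lower genes the simulated sets shared 1.504 on average and 8 at most, so the observed 3 lie within that range as a count. The count does not weigh size: AJE_06000 had log2 ratios of −4.76, −4.76 and −5.02 in A. jeotgali, A. aestuarii and A. agri. PurH, at −1.30 in A. aestuarii, would not be called there after rescaling by the median ratio. The simulation leaves out real effects, except as far as they enter its spreads, which were solved from these libraries. The independent value leaves out the shared library. Both treat genes as independent, whereas many of the 91 are neighbors, such as AJE_21280 to AJE_21530, AJE_34710 to AJE_34750 and AJE_10160 to AJE_10210. The 91 are thus not separate events, and their excess over both values is overstated. The 1 reference library cannot be split, so part of the excess may come from it.

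**Figure D4:**
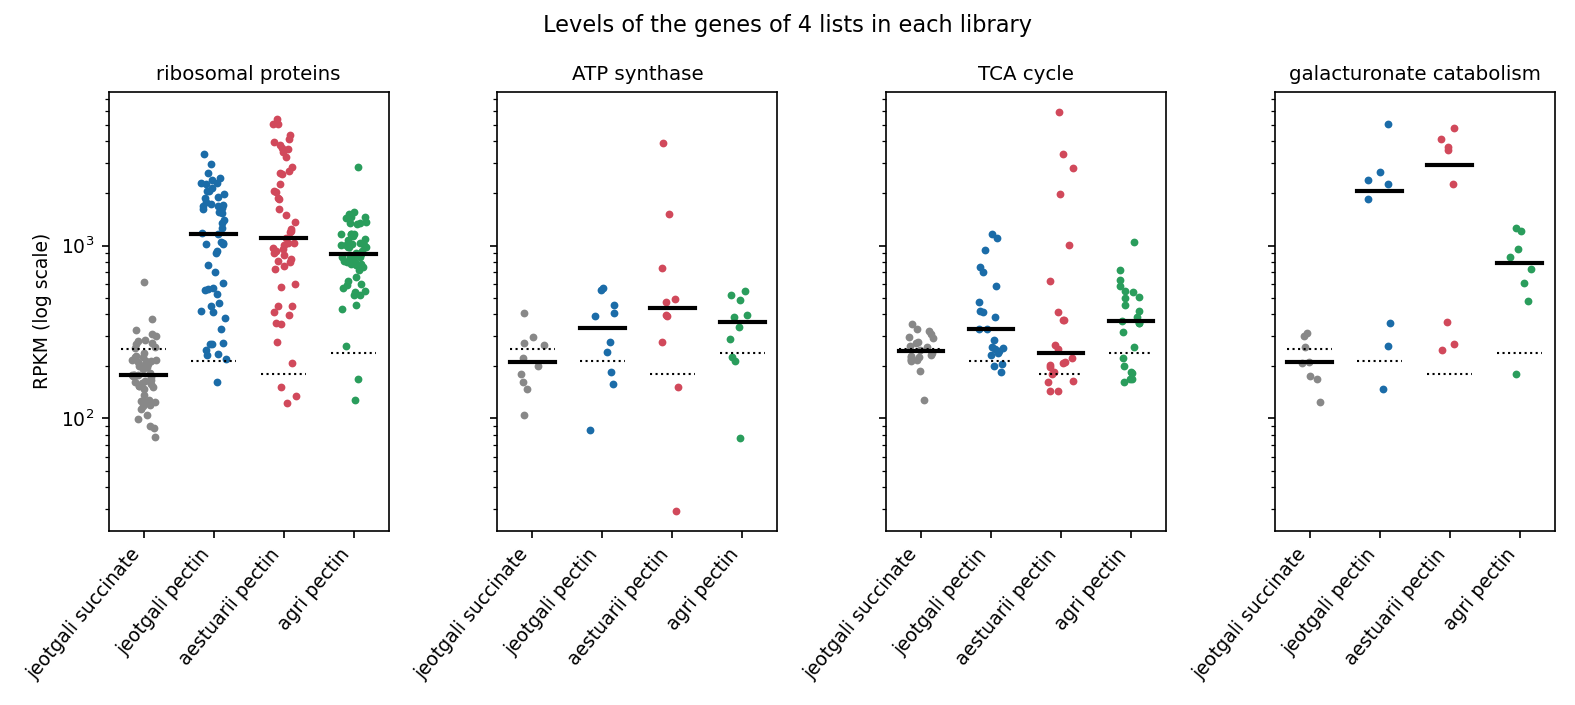
RPKM (log scale) of the genes of 4 lists in each library, 1 point per gene, with the list median (bar) and the median of all protein genes (dotted). Ribosomal protein genes lie mostly below the dotted line on succinate and above it in the pectin libraries, and galacturonate genes are highest in A. aestuarii and A. jeotgali.

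On the same carbon source, the lists of A. aestuarii outside the central 95% of random lists against A. jeotgali were the TonB and ExbB/ExbD, respiratory chain and ATP synthase lists. The TonB-dependent receptor beside urh105A was at 3571 RPKM in A. aestuarii and 636 RPKM in A. jeotgali, 5.61-fold higher (5.45 to 5.78), and ExbB (AEST_30190), which powers such receptors, was 6.33-fold higher (6.06 to 6.63). TonB and ExbB/ExbD genes had 4 of 5 higher, the respiratory chain 4 of 24 higher and ATP synthase 4 of 10 higher with 1 lower. Relative to the all-gene median of −0.19, these lists stood at 2.12, 0.66 and 0.87, at percentiles 99.1, 100 and 99.6. A cold-shock protein (AEST_24220) was 12.7-fold higher (11.9 to 13.5), maleylacetoacetate isomerase (AEST_10600) 11.8-fold (10.7 to 13.3) and FlaR (AEST_29530) 11.3-fold (10.4 to 12.4). Urh105A was 4.04-fold higher (3.92 to 4.17), uxaB 2.09-fold (2.04 to 2.14), kdgA 1.90-fold, pmeA 1.82-fold and the further aldolase 1.81-fold. The order was the opposite for uxaA, 2.23-fold lower (2.18 to 2.27), and for isocitrate lyase, 3.35-fold lower (3.29 to 3.40). The phage shock protein PspA (AEST_10460), made when the inner membrane is damaged, was 11.5-fold lower (10.7 to 12.5). The largest difference, 125-fold lower (AEST_11750), concerns a gene whose A. jeotgali counterpart is 138 bases longer. Smaller ratios were those of uxaC (1.74), kdgK (1.39), KduI (1.37), the family 28 hydrolase (1.26) and the pectate lyase AEST_12700 (1.22, interval 0.958 to 1.56), with KduD 1.42-fold lower. The galacturonate and pectin depolymerisation lists had relative medians of 0.82 and 0.78, at percentiles 90.7 and 81.7. Ribosomal proteins had 12 of 52 higher and 1 lower (relative median 0.20), glycolysis 5 of 20 higher and TonB-dependent receptors 2 of 16 (percentile 88.7). Among 2752 orthologs, 97 were higher and 133 lower, and 140 and 74 after rescaling.

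A. agri on pectin had lower levels of kdgK, kdgA, uxaB, uxaC and uxaA than A. jeotgali on pectin. KdgK (AGRI_15025) was at 610.4 RPKM against 2650.0 RPKM, 4.34-fold lower (4.12 to 4.58), uxaA 4.0-fold (3.89 to 4.12), kdgA 2.55-fold (2.40 to 2.72), uxaB 2.39-fold (2.31 to 2.49) and uxaC 1.95-fold. KduD was 2.41-fold higher (2.22 to 2.64) and KduI 1.81-fold higher. The list had 4 of 8 lower and 1 higher, and relative to the all-gene median of 0.15 it stood at −1.26 (percentile 0.63). Genes of the pectin depolymerisation list differed less, with the pectate lyase AGRI_05257 2.33-fold higher (1.90 to 2.91), AGRI_09540 1.35-fold and urh105A 1.15-fold higher. PmeA was 1.34-fold and the family 28 hydrolase 1.07-fold lower. The further aldolase AGRI_02820 was 1.21-fold higher. Catalase (AGRI_12626) was 10.4-fold lower, AhpC 3.35-fold lower and phosphoadenosine phosphosulfate reductase (AGRI_10316), which belongs to sulfate assimilation, 4.54-fold lower. Higher in A. agri were a flagellin (AGRI_00365, 8.11-fold, 7.35 to 9.05), a cell wall anchor protein (AGRI_12491, 10.9-fold) and fructose-bisphosphate aldolase (6.21-fold). Flagella and chemotaxis had 16 of 68 higher and 3 lower. The TCA cycle list, high in A. agri against succinate, was low against A. jeotgali on pectin (2 of 22 higher, 1 lower, relative median −0.39, percentile 0.5). Phage and transposable elements were lower still, with 3 of 15 higher and 6 lower (relative median −0.84, percentile 0.265). Oxidative stress had 1 of 20 higher and 5 lower and ribosomal proteins 7 of 55 higher and 13 lower. Both lists had a relative median of −0.40, at percentiles 1.99 and 2.02, and both lay within the central 95% of random lists after rescaling by the median ratio. Among 2620 orthologs, 297 were higher and 173 lower, and 214 and 231 after rescaling.

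A. aestuarii and A. agri on pectin differed in the galacturonate genes as well. KdgK was 6.04-fold higher in A. aestuarii (5.75 to 6.36), uxaB 5.00-fold (4.84 to 5.17), kdgA 4.86-fold (4.60 to 5.15), uxaC 3.39-fold and uxaA 1.80-fold, while KduD (AEST_20130) was 3.44-fold lower (3.19 to 3.73) and KduI 1.32-fold lower. Urh105A was 3.52-fold higher, pmeA 2.43-fold and the family 28 hydrolase 1.35-fold, while the pectate lyase AEST_12700 was 1.91-fold lower. The further aldolase AEST_17960 was 1.49-fold higher. A cold-shock protein (AEST_24220) was at 6993 RPKM against 277 RPKM, 25.1-fold higher (23.1 to 27.6), catalase 19.7-fold (18.9 to 20.6) and sucD 10.1-fold (9.63 to 10.7). Lower in A. aestuarii were RpoE (AEST_08200, 7.86-fold, 7.35 to 8.46), a sigma-24 factor (AEST_23900, 8.09-fold), an iron ABC transporter gene (AEST_05800, 7.86-fold) and the basal rod protein FlgF (AEST_29280, 6.91-fold). All genes had a median of −0.33, and relative to it TonB-dependent receptors stood at 0.47 (percentile 98.4) and the respiratory chain at 0.51 (percentile 99.4; 8 of 23 higher, 2 lower). The galacturonate list stood at 1.63, with 4 of 8 higher and 1 lower (percentile 95.7). Flagella and chemotaxis had 7 of 68 higher and 15 lower, and the median of −0.26 becomes 0.07 relative to all genes. Among 2563 orthologs, 145 were higher and 373 lower, and 231 and 181 after rescaling. Over all contrasts, 28 of 133 list medians lay outside the central 95% of random lists, and 5% of 133 is 6.65. That value is no chance expectation here. The 6 contrasts reuse 4 libraries, members of a list can be neighbors, and random lists draw genes independently.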

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

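The tests of even background, RNase P RNA, 6S RNA and shared copies were chosen after the results were seen, while those of abundant genes and of gene length with GC content were planned before.

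Orthologs in opposite directions numbered 7: each was at least 2-fold higher on pectin in 1 species and at least 2-fold lower in another than in A. jeotgali on succinate. The difference between species was not tested, since each has 1 library. A cold-shock protein by ortholog (AJE_23340) had log2 ratios of −0.94 in A. jeotgali, 2.72 in A. aestuarii and −1.93 in A. agri. AJE_04050, annotated as an isoamylase N-terminal domain protein, had 0.52, 1.81 and −1.65. The hypothetical AJE_09140 had −1.81, 2.15 and −0.41, and the mercury regulator MerD (AJE_21930) −1.06, 1.32 and −0.09. AJE_21550 had −0.34, −1.0 and 1.51, AJE_26410 −0.36, −1.02 and 1.24, and AJE_31080 2.24, −4.72 and −4.55. The lower values of MerD in A. jeotgali and of AJE_21550 and AJE_26410 in A. aestuarii barely pass the threshold. The all-gene medians there were −0.28 and −0.42, so these would not be called lower after rescaling by the median ratio. Orthologs outside the named genes were chosen after their values were seen.

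Genes without an ortholog lie outside every contrast between species. On pectin, 540 such protein genes of A. aestuarii and 449 of A. agri had more than 3 reads. In A. aestuarii, the pectate lyase AEST_17070 was at 7015 RPKM, rank 7 of that library and higher than any gene of the pectin depolymerisation list in the contrasts. Its neighbor AEST_17080, a hypothetical gene, was at 5506 RPKM. HlyD family secretion proteins were at 48842 RPKM (AEST_27540) and 3012 RPKM (AEST_27560). In A. agri, a siderophore receptor (AGRI_09595) was at 1210.2 RPKM and a pilin (AGRI_09195) at 1089 RPKM. The median over all genes without an ortholog was 138 RPKM in A. aestuarii and 158 RPKM in A. agri, against 189 and 249 RPKM for the others. These genes were chosen after their values were seen, and no biological explanation was tested for them.

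Ribosomal protein genes were below the library median in 44 of 55 cases on succinate and in 1 of 55, 3 of 53 and 2 of 57 in the A. jeotgali, A. aestuarii and A. agri pectin libraries. An even background of reads as the whole cause is argued against by 61.4% of 57 other strongly expressed genes, 35 of them, which kept more of their excess over the library median on succinate than 95% of 32 ribosomal genes did (limit 2.94%). The shares kept were small in both sets, with medians of 6.66% and −3.62%, so a strong flattening of the succinate library as part of the cause stays open, here and for the folds of galacturonate genes, isocitrate lyase and AhpC. In A. jeotgali, abundant genes that take reads are argued against by a median log2 ratio of 2.70 without the 20 most abundant genes (2.63 with them, quartiles 1.47 to 3.54). Gene length and GC content are argued against there by a median of 2.87 over genes matched in both (quartiles 1.68 to 3.74). For A. aestuarii and A. agri against succinate, totals without RNA genes and the 20 most abundant genes gave scaling factors of only −0.054 and 0.047 log2 units. Ribosomal protein medians there were 1100 and 894 RPKM against 179 RPKM, so abundant genes as the whole cause are argued against too. Gene length and GC content stay open for these 2 species, as do RNA degradation, the carbon source and the growth state of the cultures for each library.

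The hypothetical reading frame AJE_14740, of 135 bases, was the most abundant feature of A. jeotgali, at 264420 RPKM on pectin and 253333 RPKM on succinate. Reads shared with another listed copy are argued against, since 0% of its 36-base windows occur in another feature. A candidate explanation is RNase P RNA, the RNA part of the enzyme that trims tRNA, because an E. coli sequence recalled from memory matched over 135 bases at 86.7% identity (e-value 3.5e-37), while the other matches, of 19 and 16 bases in A. agri genes, had an e-value of 2.9. For AJE_31080, annotated as a folate enzyme and 138 and 144 bases longer than its orthologs, 6S RNA under its start cannot be told apart from a high level of the gene. The best match of a recalled E. coli 6S sequence had an e-value of 0.37 over 22 bases, too short to decide. Levels of AJE_31080 were 21577 RPKM on pectin and 4564 RPKM on succinate, against 172 and 194 RPKM for the shorter orthologs.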

How the results depend on the processing

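The alternatives with succinate rows as deposited, with lists by a gene's own annotation and with orthologs of coding lengths within 5% were chosen after seeing the data; the others were planned. Across settings, 109 counts stayed within 1.5 times the reported count and 39 did not. Of list medians, 691 stayed within counting error, 167 moved and 7 reversed, where a list counts as reversed only if it lay outside the central 95% of random lists as reported. Other lists changed sign too and count as moved or stayed. Median ratio rescaling, which shifts all genes of a contrast nearly alike, gave 102 of the moved and 3 of the reversed list medians. Of single gene ratios 2183 stayed, 617 moved and 12 reversed, with reversals counted for called genes only. The cause was not tested unless stated. Counts with other pseudocounts, minimum levels, 80% identity, coding lengths within 5% or totals without abundant genes stayed within 1.5 times.

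Counts are given as higher and lower genes. At 4-fold, which by construction calls fewer genes, they were 75 and 2 for A. jeotgali on pectin against succinate, 95 and 14 for A. aestuarii and 113 and 19 for A. agri against succinate. Between pectin libraries they were 20 and 8 (A. aestuarii against A. jeotgali), 46 and 16 (A. agri against A. jeotgali) and 34 and 51 (A. aestuarii against A. agri), and 40 genes were higher in all 3 species. Pairing by unique product text, which tests fewer genes, gave 65 and 79, 90 and 47, 30 and 28, 62 and 45, and 84 and 173 in the 5 contrasts between species, in the same order. Rescaling by the median ratio and by the trimmed mean each gave 20 lower genes in A. jeotgali, 294 and 88 for A. aestuarii against succinate and 74 lower genes for A. aestuarii against A. jeotgali on pectin. For A. aestuarii against A. agri the median ratio gave 231 and 181, the trimmed mean 235 and 177. With succinate rows as deposited, which pair values of different genes, the counts were 375 and 590 in A. jeotgali, 562 lower genes for A. aestuarii and 164 higher in all 3 species.

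Among single genes with rows as deposited, log2 ratios reversed to 1.35 (AJE_07530), 5.15 (AJE_08220), 3.70 (AJE_19830), 0.35 (AJE_15210), 1.63 (AJE_30040), 0.87 (AEST_29350) and −0.47 (AEST_01020). The same setting gave 1.17 (AGRI_00895), −0.85 (AGRI_13840), −2.46 (AGRI_00645) and 3.14 (AGRI_02730). Pairing by product text gave 1.22 for the receptor AGRI_06197 (−1.30 as reported), because it pairs another gene. In A. jeotgali, median ratio rescaling turned the medians of lists outside that range to 0.12 for flagella, 0.24 for fatty acid oxidation and 0.11 for rRNA and tRNA genes. Rows as deposited gave −0.30 for ATP synthase, −0.057 for oxidative stress and 0.38 for flagella, and lists by own annotation gave 0.14 for fatty acid oxidation. No paired analysis was possible because each group has 1 library. Depth limits little: in the simulated data every gene set to 3-fold was called, whereas 1.5-fold is below the threshold.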

Other observations

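Some strongly expressed genes fall in none of the lists. A CBS-domain protein, AEST_26700 in A. aestuarii, was at 32641 RPKM, and its orthologs were at 5562 RPKM (AJE_20880, 1264 RPKM on succinate) and 8324 RPKM (AGRI_11892, the highest value of A. agri). Elongation factor Tu (AJE_21140) was at 1419, 8071 and 1748 RPKM on pectin in A. jeotgali, A. aestuarii and A. agri and at 304 RPKM on succinate; a further copy is listed (AJE_21260, 1376 RPKM on pectin), so its values are uncertain. The hypothetical AJE_06000, the most abundant gene on succinate after AJE_14740 at 24076 RPKM, was at 885, 889 and 741 RPKM in the pectin libraries. These genes were chosen after their values were seen.

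The libraries differ in the spread of their values. The 95th percentile over the median was 1.75 on succinate and 2.63, 3.40 and 3.58 on pectin in A. jeotgali, A. aestuarii and A. agri. The 5% most abundant genes took 22.7%, 30.05%, 40.1% and 24.02% of reads in the same order. With reads spread evenly over the listed features, all genes of a library would have the same RPKM. The median protein gene was at 86.3%, 73.8%, 58.9% and 76.0% of that value, and the 5th percentile at 45.9%, 35.8%, 25.9% and 28.3%. An even background was not measured in any library, and it would make the folds of genes near the median smaller. Across genes, which are not independent replicates, the Spearman correlation of level with GC content was −0.06, −0.03, 0.26 and 0.32. All rRNA features, 6, 4 and 3 in the 3 tables, were listed at 0. In the authors' deposited table, 372 fold changes were at least 2 and 618 at most 0.5, and 143 of those 372 features were among the 171 that were higher in the restored order.

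Both tests of the row order were chosen after the result was seen. The succinate values met what another row order than that of the genes requires, since 100% of them are whole reads in the order of region ends. An unrelated set of transcripts on succinate, with rows in place, is argued against because 2.78% are whole reads as deposited. Where in the preparation of the table the order was lost stays open.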
